A study of Homo sapiens with 15 samples.

How the data were processed

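Gene expression was measured with Illumina HT-12 bead arrays in HEK293 cells, an established human embryonic kidney line. Per the labels, 500000 cells per well of a 6-well plate were seeded in medium with 10% serum and transfected 24 hours later with 50 pmol of a mirVana mimic in Lipofectamine RNAiMAX, and total RNA was taken on day 2. The 15 arrays form 5 groups of 3: a negative control mimic, miR-142-3p, miR-142-3p-1, miR-K10a and miR-K10a+1. The labels do not say whether replicates came from separate cultures or which arrays shared a slide.

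The authors deposited a table of signal intensity per probe and array that was not normalized between arrays, and it was the input here. The authors deposited beside each intensity a detection p-value, a rank against negative control beads. A second table that the authors deposited holds normalized signal intensity on a linear scale, with the same distribution on every array and the same order of probes as the raw signal of the same sample. It was made with lumi 2.15.1 per the submitters' processing notes; its normalization steps are not given in the sources used here, and it served as an alternative. Control probes were not in the tables.

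Of 47323 probes, 30113 had 1 gene symbol, 8 had several and 17202 had none; the symbols covered 20046 genes, and 99.9% of the annotated probes were matched to a current symbol by Entrez gene number. Raw signal was background corrected by the normal-exponential model from detection p (offset 16), quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Tables were read with the data.table package (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Each gene was represented by its probe with the highest mean, and genes detected at p below 0.01 on all 3 arrays of at least 1 group were tested, which left 10413. Probes without a symbol were fitted apart.

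A group-means model over all 15 arrays was fitted with limma and its variance moderated by eBayes (10 residual and 6.37 prior degrees of freedom). The comparisons were each mimic against the control, the 2 isomiR pairs, the 4 pairs across families, the difference between the isomiR contrasts, and a moderated F-test over the 5 groups. The Benjamini-Hochberg method adjusted p over all genes of a comparison, with a threshold of 0.05. An error beside a log2 fold change is its standard error from this fit, with n = 3 arrays per group. On simulated data with 100 genes shifted by 0.5 log2, 61% were recovered in the comparison of miR-142-3p with the control and 64% in that of miR-K10a+1 with miR-K10a; for shifts of 1 log2 both shares were 99%. Of the calls on the simulated data, 8.05% and 4.12% were false.

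Choices were made before the data were examined unless stated otherwise. They include 25 gene lists: actin dynamics regulators, literature targets of miR-142-3p and of miR-K10a, G2/M genes, S phase genes, interferon-stimulated genes, p53 targets, unfolded protein and integrated stress response genes, cholesterol synthesis genes, cytosolic ribosomal proteins, hypoxia and glycolysis genes, oxidative phosphorylation subunits, TGF-beta pathway and target genes, small RNA silencing machinery, cytosolic heat shock genes, immediate early genes, Wnt pathway targets, integrins and focal adhesion genes, endocytosis and vesicle trafficking genes, apoptosis regulators, canonical replication-dependent histones, and markers of hematopoietic, fibroblast and mesenchymal, epithelial and neuronal cells. Lists with at least 5 tested members were tested with camera of limma, which compares a list with all other genes (preset correlation between genes 0.01), adjusted over lists, and again with an estimated correlation. The fry test asked whether a list's genes move one way on balance or in either direction, without comparing them with other genes.

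Named genes followed a rule. For each mimic against the control these were the 8 lowest and 6 highest log2 fold changes past the threshold whose 3 arrays of one group all lay beyond the 3 of the other, up to 6 actin list members, up to 4 literature targets of miR-142-3p, and up to 4 members of any other list past camera. For the isomiR pairs they were the 8 lowest and 8 highest with up to 4 actin list members, and across families the 3 lowest and 3 highest. Both literature targets of miR-K10a were to be named throughout, but for miR-142-3p and miR-142-3p-1 against the control only TGFBR2 is given here. Up to 2 genes not detected in 1 of the groups were named with a lower bound of their fold. Symbols of uncharacterized loci were not named.

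The alternatives were the deposited normalized values, no background correction, an offset of 50, median scaling or cyclic loess in place of quantiles, no detection filter, detection on all 15 arrays, the mean of all probes of a gene, every probe on its own, trend and robust eBayes, array weights, the replicate number as a block, a log2 fold change of at least 0.5 as well, only the 6 arrays compared, and leaving out each array. The mean of all probes of a gene takes in probes that did not pass the detection filter, which can shrink a fold change. It is therefore not a second measurement of the gene. The correlation of responses was set beside 100 simulated sets of unchanged groups with shared controls, drawn from the spread of arrays within all 5 groups. Predicted 3 prime UTR seed sites were left out because no transcript sequences were available, and a slide block was left out because the files name no slide.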

Results

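Total RNA from HEK293 cells transfected with a synthetic microRNA (a mimic) or with a negative control mimic was profiled on 15 bead arrays, 3 in each of 5 groups. miR-142-3p is a human microRNA of blood cells, and miR-K10a is encoded by Kaposi's sarcoma-associated herpesvirus. miR-142-3p-1 and miR-K10a+1 are isomiRs, variants of the same microRNA that differ at an end; the labels do not give their sequences. The series asks how the isomiRs of both microRNAs differ in the genes they regulate. Each array detected between 16018 and 17765 of 47323 probes, and the median raw signal of an array lay between 98.6 and 108.7. Of 10413 genes tested, 4019 differed among the 5 groups in the limma F-test. Fold changes are on the log2 scale with their standard error (n = 3 arrays per group), and the number of arrays limits their precision. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples.

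Cells that received miR-142-3p had less mRNA of 12 of 15 genes that the literature names as targets of this microRNA, and more of 4 of 5 epithelial markers, than cells that received the control mimic. The p53 and interferon lists were also higher, but these calls ended with an estimated correlation (adjusted p = 0.179 and 0.0883). WASL, an activator of branched actin assembly (Entrez gene 8976, chromosome 7), had a log2 fold change of -1.81 ± 0.09 (adjusted p = 3.04e-09). The lowest value was that of SLC49A4, a transporter of the lysosomal membrane (Entrez gene 84925, chromosome 3), at -1.92 ± 0.12 (adjusted p = 2.17e-08). The highest was that of PTPMT1, a mitochondrial phosphatase, at 1.38 ± 0.10 (adjusted p = 4.66e-07), and CDKN1A, which encodes the cell cycle inhibitor p21, stood at 1.17 ± 0.11 (adjusted p = 3.59e-06). In all, 729 genes were lower and 828 higher with miR-142-3p.

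Of the 15 measured literature targets of miR-142-3p, 12 fell and none rose, and 12 fell when adjusted over the list alone (camera adjusted p = 8.11e-13, and adjusted p = 0.000988 with an estimated correlation). The list may hold genes first reported from these samples, so it is not independent evidence of its direction. Besides WASL, the members TWF1, which binds actin monomers, CLIC4, an intracellular chloride channel protein, and CFL2, which severs actin filaments, fell by 1.20 ± 0.15, 1.12 ± 0.11 and 0.84 ± 0.14 on the log2 scale; with the mean of all probes CFL2 was at -0.36 (adjusted p = 0.0503). Other large falls were those of PNO1, a ribosome assembly factor (-1.55 ± 0.09), MANBAL (-1.52 ± 0.09), TSEN34, a subunit of the tRNA splicing endonuclease (-1.39 ± 0.08), PPP1R14C, a phosphatase inhibitor (-1.32 ± 0.11), VAMP3, a vesicle fusion protein (-1.31 ± 0.08), and the Src family kinase YES1 (-1.29 ± 0.14). The wider list of 83 actin dynamics regulators moved both ways: 10 fell and 6 rose (adjusted over the list alone, 11 and 10), and camera gave adjusted p = 0.764. Among its members, the cortical actin protein CTTN fell by 0.68 ± 0.11 on the log2 scale, while PIP4K2A, a phosphoinositide kinase, rose by 0.79 ± 0.08 (0.77 and 0.36 for its 2 other detected probes, adjusted p = 0.00052 and 0.213). ELMO1 was at 0.68 ± 0.14, but at 0.09 with the mean of its probes (adjusted p = 0.533).

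Epithelial markers rose with miR-142-3p: 4 of 5 measured members were higher and none lower, also when adjusted over the list alone (camera adjusted p = 0.000142, and adjusted p = 0.0144 with an estimated correlation). EPCAM, an adhesion molecule, rose by 0.95 ± 0.12, and the keratins KRT8 and KRT18 by 0.87 ± 0.15 and 0.76 ± 0.10. The other detected probe of KRT18 had 0.021 (adjusted p = 0.946). The 4th was MUC1 at 0.53 ± 0.13, which missed the threshold without Control replicate 1 and miR-142-3p replicate 3 (adjusted p = 0.0517 and 0.0514) and with the mean of its probes (0.10, adjusted p = 0.498). CDH1, the remaining member, had 0.19 ± 0.14 (adjusted p = 0.402). Of 22 interferon-stimulated genes 5 rose and none fell, and 7 rose when adjusted over the list alone (camera adjusted p = 0.0118, but adjusted p = 0.0883 with an estimated correlation). SAMD9 and SP110 stood at 0.90 ± 0.13 and 0.70 ± 0.12, and the 2 other detected probes of SP110 had 0.40 and 0.83 (adjusted p = 0.368 and 0.000505). ISG15 (0.50 ± 0.15) missed the threshold without Control replicates 2 and 3 and miR-142-3p replicates 1 and 3 (adjusted p = 0.117, 0.0634, 0.137 and 0.0542). ISG20 (0.49 ± 0.16) missed it without Control replicates 1 and 3 and miR-142-3p replicates 1, 2 and 3 (adjusted p = 0.195, 0.0705, 0.126, 0.124 and 0.0542) and with the deposited normalized values (0.15, adjusted p = 0.123). Of 23 p53 targets 6 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0259, but adjusted p = 0.179 with an estimated correlation). The list also missed the threshold without miR-142-3p replicate 1 (adjusted p = 0.0567). After CDKN1A came TP53I3 (0.63 ± 0.12), GADD45A, a DNA damage response gene (0.59 ± 0.12), and the apoptosis effector BAX (0.50 ± 0.10), which with the mean of its probes had 0.22 (adjusted p = 0.111).

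Further genes raised by miR-142-3p were BEGAIN (1.24 ± 0.12), the phospholipid-binding protein gene ANXA1 (1.23 ± 0.15), LZTFL1, a regulator of ciliary traffic (1.16 ± 0.10), and AMH, which encodes anti-Müllerian hormone (1.15 ± 0.13). HSPB8, a small heat shock protein gene not detected in the control, was at least 1.77-fold higher, and AKT1S1, not detected with miR-142-3p, at least 1.72-fold lower. The count of 1557 genes was 987 without miR-142-3p replicate 2 and 859 with median scaling (348 lower, 511 higher). It was 1028 with only the 6 arrays compared and 584 when a log2 fold change of at least 0.5 was also asked.

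**Figure D1:**
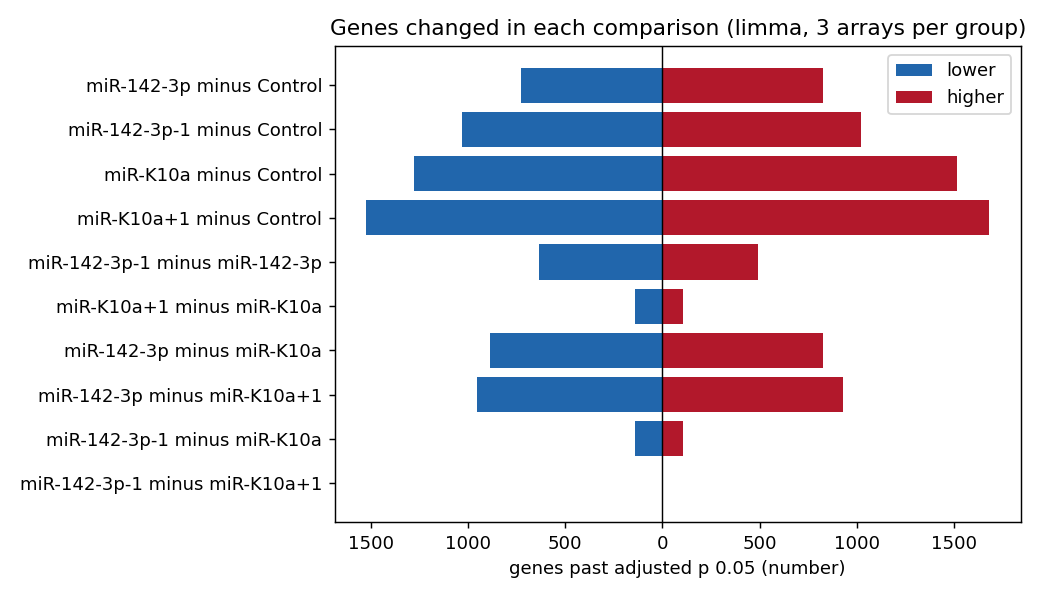
Number of genes past the limma threshold (x axis) in each of the 10 comparisons (y axis), lower to the left and higher to the right, with 3 arrays per group. The bars run from 1524 lower and 1681 higher genes for miR-K10a+1 against the control to 0 lower and 3 higher for miR-142-3p-1 against miR-K10a+1.

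The isomiR miR-142-3p-1 lowered cyclin D1 and raised smooth muscle actin relative to the control mimic. The p53 and S phase lists were higher by camera, with 12 of 23 and 8 of 36 members past the test. The hypoxia and glycolysis list was lower, but this call ended with an estimated correlation (adjusted p = 0.184). ACTA2, smooth muscle actin (Entrez gene 59, chromosome 10), rose by 2.05 ± 0.11 (adjusted p = 2.3e-08), the largest rise. TLCD1, a membrane protein (Entrez gene 116238, chromosome 17), fell by 1.96 ± 0.12 on the log2 scale (adjusted p = 8.63e-08), and CCND1, cyclin D1, by 1.28 ± 0.10 (adjusted p = 6.65e-07). In all, 1029 genes were lower and 1023 higher.

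After TLCD1, low values with miR-142-3p-1 were those of YES1 (-1.76 ± 0.14), RELL1 (-1.50 ± 0.15), CRABP2, a retinoic acid binding protein (-1.49 ± 0.14), the G protein subunit GNG12 (-1.40 ± 0.19), and SGPP2, a sphingosine phosphate phosphatase (-1.29 ± 0.13). Of the literature targets of miR-142-3p 6 fell and none rose, and 9 fell when adjusted over the list alone (camera adjusted p = 0.000614, and adjusted p = 0.0386 with an estimated correlation). WASL fell by 1.17 ± 0.09 on the log2 scale and TWF1 by 0.77 ± 0.15. CFL2 (-0.87 ± 0.14) and the cytokine receptor subunit IL6ST (-0.58 ± 0.10) missed the threshold with the mean of all probes (adjusted p = 0.0521 and 0.0733). Actin dynamics regulators again moved both ways, 16 lower and 10 higher (adjusted over the list alone, 16 and 13; camera adjusted p = 0.792). RDX, radixin, which ties actin to the membrane, fell by 1.26 ± 0.13 and ARPC1A, a subunit of the Arp2/3 complex, by 0.88 ± 0.11, while PIP4K2A rose by 0.92 ± 0.08. The 2 other detected probes of PIP4K2A had 0.82 and 0.14 (adjusted p = 0.000271 and 0.654).

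Of the p53 targets 12 rose with miR-142-3p-1 and 1 fell, and 14 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.13e-05, and adjusted p = 0.0206 with an estimated correlation). CDKN1A, SPATA18, a mitochondrial quality control gene, DDB2, a DNA repair gene, and BAX rose by 1.43 ± 0.11, 1.28 ± 0.11, 1.07 ± 0.17 and 1.02 ± 0.10. The other detected probe of BAX had 0.36 (adjusted p = 0.162). Of 36 S phase genes 8 rose and none fell, the same numbers as when adjusted over the list alone (camera adjusted p = 0.000705, and adjusted p = 0.0206 with an estimated correlation). CCNE1, cyclin E1, rose by 0.88 ± 0.09, the replication licensing factor CDT1 by 0.56 ± 0.12, and GINS3 and LIG1 by 0.55 ± 0.08 and 0.55 ± 0.11. Of 31 hypoxia and glycolysis genes 11 fell and none rose, and 14 fell and 2 rose when adjusted over the list alone (camera adjusted p = 4.99e-05, but adjusted p = 0.184 with an estimated correlation). BNIP3, which acts in the removal of mitochondria, fell by 1.15 ± 0.14, ANKRD37 by 0.67 ± 0.14, the glycolytic enzyme PFKP by 0.61 ± 0.08 and NDRG1 by 0.59 ± 0.10 on the log2 scale. PTPMT1 (1.49 ± 0.10) and ANXA1 (1.42 ± 0.15) were also among the highest values. FES, a tyrosine kinase gene, and PPID, a cyclophilin gene, were not detected in the control and were at least 1.79-fold and 1.63-fold higher. The count of 2052 genes was 1341 with median scaling (865 lower, 476 higher) and 830 when a log2 fold change of at least 0.5 was also asked.

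The viral miR-K10a raised smooth muscle actin and p21 and lowered its literature targets relative to the control mimic. Of the 24 lists tested 5 passed camera with the preset correlation and 0 with an estimated one. ACTA2 rose by 1.75 ± 0.11 (adjusted p = 1.37e-07) and CDKN1A by 1.43 ± 0.11 (adjusted p = 6.72e-07). CBY1, an antagonist of beta-catenin (Entrez gene 25776, chromosome 22), fell by 1.51 ± 0.08 on the log2 scale (adjusted p = 1.13e-08). Of the literature targets of miR-K10a, TNFRSF12A, the receptor of the cytokine TWEAK, fell by 1.32 ± 0.20 (adjusted p = 0.000231) and TGFBR2, a TGF-beta receptor, by 0.45 ± 0.13 (adjusted p = 0.0174), both also when adjusted over the list alone. TGFBR2 missed the threshold without Control replicate 2 and miR-K10a replicate 3 (adjusted p = 0.0501 and 0.0936). Against the control TGFBR2 also had -0.38 with miR-142-3p and -0.37 with miR-142-3p-1. Its other detected probe had -0.43 and -0.33 there (adjusted p = 0.0186 and 0.0538). TNFRSF12A was higher with miR-142-3p than with miR-K10a, but did not pass the threshold between miR-142-3p-1 and miR-K10a. In all, 1276 genes were lower and 1515 higher.

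The lowest value with miR-K10a was that of SNAR-A1, one of a family of near-identical small noncoding RNAs (-1.74 ± 0.31). It was followed, besides CBY1, by TLCD1 (-1.48 ± 0.12), EPAS1, the hypoxia-inducible factor 2 alpha (-1.48 ± 0.17), RELL1 (-1.42 ± 0.15), the laminin chain gene LAMC1 (-1.37 ± 0.10), SGPP2 (-1.35 ± 0.13) and the glucose phosphatase gene G6PC3 (-1.33 ± 0.11). Literature targets of the human miR-142-3p included 7 that fell and 1 that rose, the same numbers as when adjusted over the list alone (camera adjusted p = 0.00585, but adjusted p = 0.079 with an estimated correlation). CFL2 fell by 1.06 ± 0.14, WASL by 0.86 ± 0.09 and TWF1 by 0.61 ± 0.15 on the log2 scale, and CLIC4 was at -0.56 ± 0.11 (-0.26 and adjusted p = 0.0961 with the mean of its probes). Among actin dynamics regulators 19 fell and 14 rose (adjusted over the list alone, 20 and 16; camera adjusted p = 0.339). Among them NCKAP1, of the WAVE complex, fell by 0.76 ± 0.11 and WASF3, of the same complex, rose by 1.00 ± 0.12.

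Of the p53 targets 11 rose with miR-K10a and 1 fell, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000211, but adjusted p = 0.079 with an estimated correlation). SPATA18, BAX and TP53I3 rose by 1.14 ± 0.11, 1.07 ± 0.10 and 0.94 ± 0.12. S phase genes included 9 that rose and 2 that fell, also when adjusted over the list alone (camera adjusted p = 0.037, but adjusted p = 0.079 with an estimated correlation and 0.0522 with cyclic loess). That call also ended without Control replicates 2 and 3 and miR-K10a replicate 1 (adjusted p = 0.0551, 0.0552 and 0.066). CCNE1, CDT1 and the helicase subunit MCM6 rose by 1.01 ± 0.09, 0.97 ± 0.12 and 0.55 ± 0.10, and the repair enzyme gene UNG fell by 0.55 ± 0.10. Hypoxia and glycolysis genes included 10 that fell and 2 that rose, and 11 and 3 when adjusted over the list alone (camera adjusted p = 0.0137, but adjusted p = 0.296 with an estimated correlation). The hypoxia call ended without Control replicate 3 (adjusted p = 0.0552). The glycolytic enzymes PKM and PFKP fell by 0.73 ± 0.11 and 0.64 ± 0.08 and BNIP3L by 0.69 ± 0.12 (-0.39 and adjusted p = 0.12 for its other detected probe), while the glucose transporter SLC2A3 rose by 0.65 ± 0.13. Of 12 canonical histone genes 4 rose and none fell, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.049, but adjusted p = 0.296 with an estimated correlation). The histone call also ended without Control replicates 2 and 3 and miR-K10a replicates 1 and 2 (adjusted p = 0.0813, 0.106, 0.0504 and 0.0837). The same held with cyclic loess (adjusted p = 0.0522), the replicate block (adjusted p = 0.0546) and the deposited normalized values (adjusted p = 0.0607). H2BC11 stood at 0.53 ± 0.13; H2AC20 (0.49 ± 0.11) and H2AC18 (0.38 ± 0.10) missed the threshold with median scaling (adjusted p = 0.0659 and 0.162), and H2BC5 (0.27 ± 0.09) missed it without Control replicates 1, 2 and 3 and miR-K10a replicates 1, 2 and 3 (adjusted p = 0.0538, 0.116, 0.0809, 0.112, 0.0767 and 0.0812) and with median scaling (0.13, adjusted p = 0.501).

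PTPMT1 (1.39 ± 0.10), the glutathione transferase gene GSTO2 (1.27 ± 0.12) and the signalling ligand gene WNT3 (1.13 ± 0.16) were also among the highest values with miR-K10a. PPID was at least 1.60-fold higher, and LIFR, a cytokine receptor gene not detected with miR-K10a, at least 1.57-fold lower. With median scaling 1565 genes were lower and 526 higher (25.2% higher, against 54.3%), and 1045 of the 2791 genes remained when a log2 fold change of at least 0.5 was also asked.

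With miR-K10a+1 more genes changed than in any other comparison, 1524 lower and 1681 higher than with the control mimic. ACTA2 rose by 1.95 ± 0.11 (adjusted p = 2.43e-08) and PTPMT1 by 1.67 ± 0.10 (adjusted p = 3.59e-08). TLCD1 fell by 1.99 ± 0.12 on the log2 scale (adjusted p = 3.59e-08), YES1 by 1.92 ± 0.14 (adjusted p = 1.6e-07), and CPS1, the first enzyme of the urea cycle (Entrez gene 1373, chromosome 2), by 1.69 ± 0.11 (adjusted p = 3.97e-08). Of the literature targets of miR-K10a, TNFRSF12A fell by 1.03 ± 0.20 (adjusted p = 0.0011), and TGFBR2 had -0.16 ± 0.13 (adjusted p = 0.365). The other detected probe of TGFBR2 was past the threshold, at -0.43 (adjusted p = 0.0101).

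Other low values with miR-K10a+1 were those of SNAR-A1 (-1.84 ± 0.31), RELL1 (-1.63 ± 0.15), SERF1B, which has a near-identical copy in the genome (-1.63 ± 0.10), DHRS7B (-1.62 ± 0.12) and the small nucleolar RNA SNORA79 (-1.53 ± 0.36). Literature targets of miR-142-3p included 8 that fell and none that rose, and 9 fell when adjusted over the list alone (camera adjusted p = 0.000799, but adjusted p = 0.0515 with an estimated correlation). WASL fell by 1.21 ± 0.09, CFL2 by 1.13 ± 0.14, TWF1 by 0.74 ± 0.15 and the adenylate cyclase gene ADCY9 by 0.59 ± 0.12 on the log2 scale. Of the actin dynamics regulators 20 fell and 15 rose (adjusted over the list alone, 20 and 16; camera adjusted p = 0.427). There RDX fell by 1.18 ± 0.13, ARPC1A by 1.11 ± 0.11, and CYFIP2, of the WAVE complex, rose by 0.91 ± 0.12 (0.21 and adjusted p = 0.176 for its other detected probe).

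S phase genes included 13 that rose with miR-K10a+1 and 2 that fell, and 16 and 2 when adjusted over the list alone (camera adjusted p = 0.00148, and adjusted p = 0.0399 with an estimated correlation). CDT1, CCNE1, GINS3 and CDC45, which acts at the replication fork, rose by 1.02 ± 0.12, 1.01 ± 0.09, 0.56 ± 0.08 and 0.55 ± 0.12, and the transcription factor gene E2F2, outside that list, by 1.24 ± 0.10. Among p53 targets 11 rose and 1 fell, and 12 and 1 when adjusted over the list alone (camera adjusted p = 0.000799, but adjusted p = 0.0515 with an estimated correlation). CDKN1A, SPATA18, BAX and DDB2 rose by 1.28 ± 0.11, 1.13 ± 0.11, 0.93 ± 0.10 and 0.88 ± 0.17, and the other detected probe of BAX had 0.37 (adjusted p = 0.123). Hypoxia and glycolysis genes included 14 that fell and 1 that rose, and 15 and 1 when adjusted over the list alone (camera adjusted p = 0.000799, but adjusted p = 0.27 with an estimated correlation). BNIP3, ENO2, PKM and BNIP3L fell by 1.12 ± 0.14, 0.69 ± 0.11, 0.67 ± 0.11 and 0.65 ± 0.12 on the log2 scale. The other detected probe of BNIP3L had -0.17 (adjusted p = 0.511). The histone chaperone partner HIRIP3 (1.19 ± 0.12) and ZNF512B (1.16 ± 0.13) were also among the highest values. GNG12 and the growth factor receptor gene EGFR were not detected with miR-K10a+1 and were at least 2.32-fold and 2.148-fold lower.

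The remaining lists passed camera in none of the 10 comparisons. With miR-K10a+1 against the control, the members lower and higher were 4 and 10 of 43 G2/M genes (adjusted p = 0.411), 3 and 2 of 27 unfolded protein and integrated stress response genes (0.189), 3 and 4 of 18 cholesterol synthesis genes (0.84), and 7 and 6 of 52 oxidative phosphorylation subunits (0.451). They were 7 and 3 of 20 TGF-beta pathway and target genes (0.302), 2 and 8 of 22 genes of the small RNA silencing machinery (0.189), 7 and 2 of 32 integrins and focal adhesion genes (0.154), 12 and 6 of 44 endocytosis and vesicle trafficking genes (0.397) and 3 and 5 of 24 apoptosis regulators (0.568). Markers of other cell types gave 1 and 0 of 5 for hematopoietic cells (0.84), 0 and 3 of 7 for fibroblast and mesenchymal cells (0.144) and 3 and 1 of 9 for neurons (0.189). Adjusted over the list alone, the counts in the same order were 4 and 10, 3 and 2, 3 and 5, 6 and 6, 7 and 3, 2 and 9, 7 and 2, 12 and 6, 3 and 6, 1 and 0, 0 and 4, and 3 and 1. With median scaling, 1511 genes were lower and 873 higher with miR-K10a+1 (36.6% higher, against 52.4%), and 1287 of the 3205 genes remained when a log2 fold change of at least 0.5 was also asked.

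**Figure D2:**
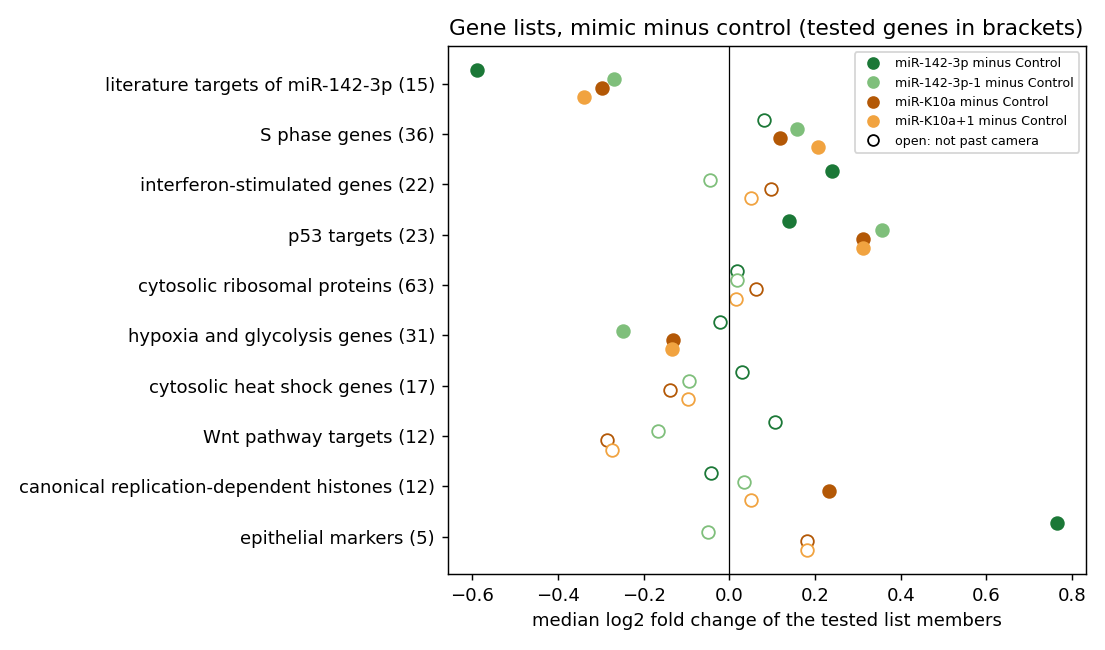
Median log2 fold change against the control (x axis) of the measured members of 10 gene lists (y axis, number of members in brackets) for the 4 mimics (colours), with filled points for lists past camera with the preset correlation and open points for the others. Literature targets of miR-142-3p lie lowest with miR-142-3p (median -0.59), and epithelial markers lie highest with it (median 0.76).

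**Figure D3:**
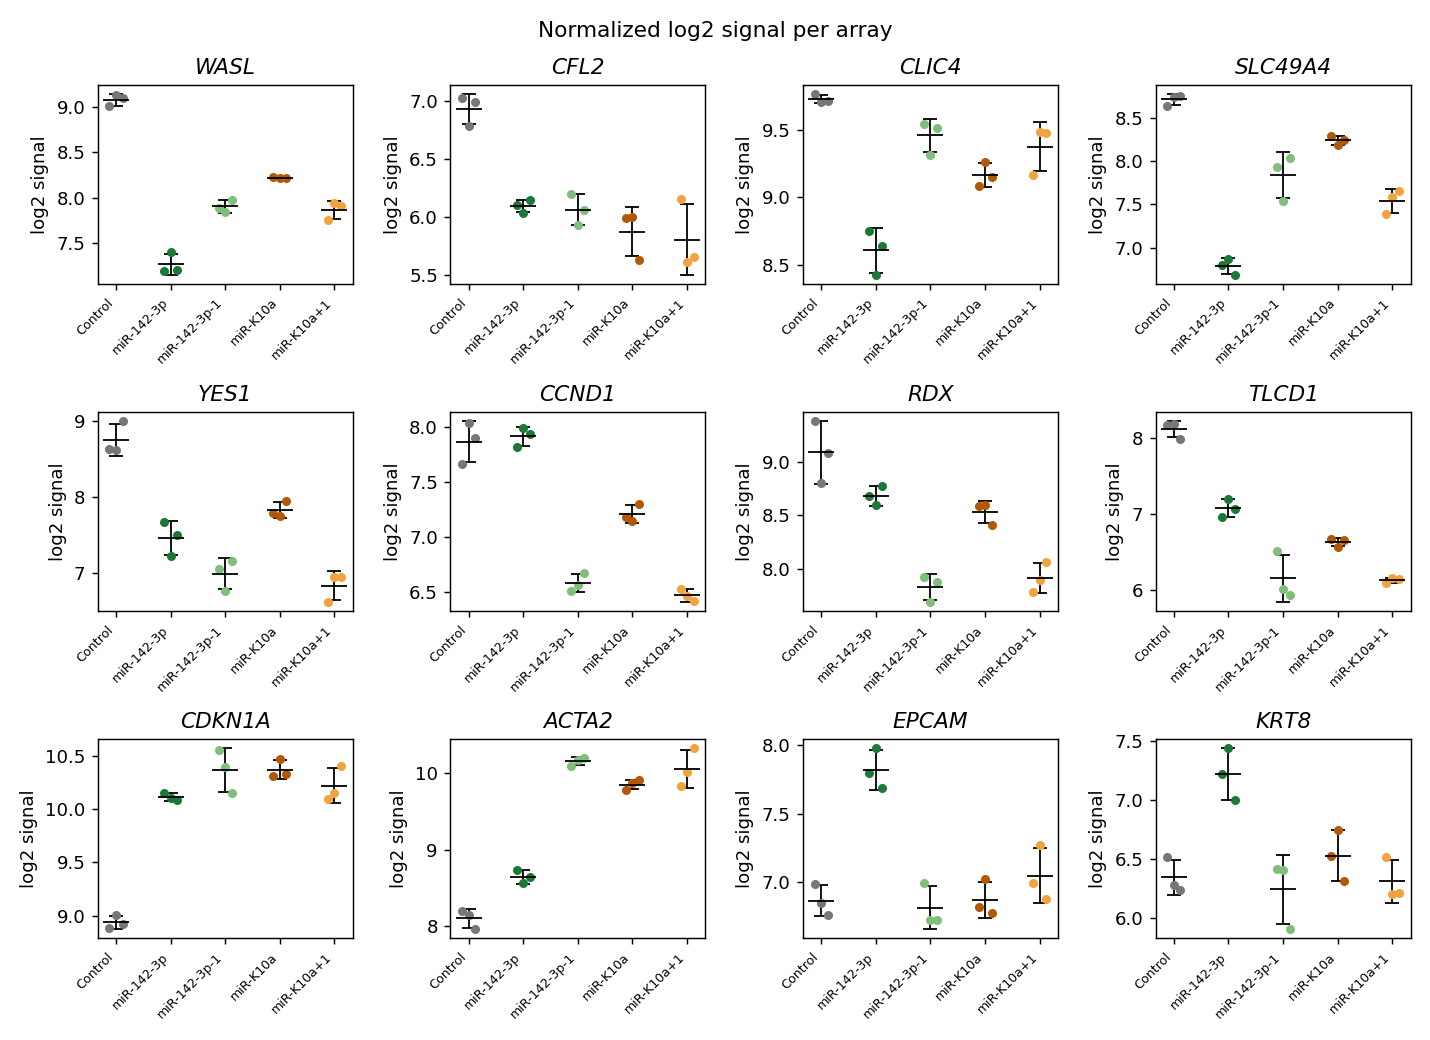
Normalized log2 signal (y axis) of 12 genes on each array (points) in the 5 groups (x axis), with the mean and standard deviation of 3 arrays (bars). WASL is lowest with miR-142-3p, CCND1 is low with miR-142-3p-1 and miR-K10a+1, and EPCAM and KRT8 are high with miR-142-3p.

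The isomiRs of miR-142-3p were compared directly to ask which genes tell them apart. Cyclin D1 (CCND1, Entrez gene 595, chromosome 11) was lower with miR-142-3p-1 than with miR-142-3p (-1.33 ± 0.10, adjusted p = 9.48e-07) and ACTA2 was higher (1.51 ± 0.11, adjusted p = 9.48e-07). The actin regulators WASL (0.63 ± 0.09, adjusted p = 0.000237) and CTTN (0.88 ± 0.11, adjusted p = 0.000192) were higher with miR-142-3p-1, whereas RDX (-0.86 ± 0.13, adjusted p = 0.000449) and ARPC1A (-0.75 ± 0.11, adjusted p = 0.000292) were lower. The epithelial, interferon and Wnt lists were lower with miR-142-3p-1 by camera, with 4 of 5, 8 of 22 and 3 of 12 members past the test. The hypoxia list was also lower and the p53 list higher, but these calls ended with an estimated correlation (adjusted p = 0.106 and 0.0615). In all, 634 genes were lower and 492 higher.

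The literature targets of miR-142-3p were higher with miR-142-3p-1, 6 of 15, with none lower, and 9 when adjusted over the list alone (camera adjusted p = 2.21e-05, and adjusted p = 0.0149 with an estimated correlation). As this list may hold genes first reported from these samples, the call is not independent evidence. CLIC4 and BOD1, a mitotic regulator, were higher by 0.85 ± 0.11 and 0.65 ± 0.09, and RAC1 by 0.55 ± 0.10 (0.17 and adjusted p = 0.235 with the mean of its probes). The 2 other detected probes of CLIC4 had 0.13 and 0.63 (adjusted p = 0.467 and 0.0675). Of the 5 epithelial markers 4 were lower and none higher, also when adjusted over the list alone (camera adjusted p = 2.21e-05, and adjusted p = 0.0149 with an estimated correlation): CDH1, which encodes E-cadherin (-1.02 ± 0.14), EPCAM (-1.003 ± 0.12), KRT8 (-0.97 ± 0.15) and KRT18 (-0.46 ± 0.10; -0.26 and adjusted p = 0.15 with the mean of its probes). CDH1 was detected on 13 of the 15 arrays, and against the control it did not pass with miR-142-3p (0.19 ± 0.14, adjusted p = 0.402). Of the interferon-stimulated genes 8 were lower and none higher, and 10 and 1 when adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.038 with an estimated correlation). IFI35, IFIT1 and SP110 had -0.77 ± 0.16, -0.63 ± 0.11 and -0.62 ± 0.12, where the 2 other detected probes of SP110 had -0.60 and -0.70 (adjusted p = 0.192 and 0.00224). ISG15 had -0.59 ± 0.15 but missed the threshold without miR-142-3p replicate 1 and miR-142-3p-1 replicates 1 and 2 (adjusted p = 0.086, 0.0538 and 0.0583). Of 12 Wnt pathway targets 3 were lower and none higher, and 4 when adjusted over the list alone (camera adjusted p = 0.00325, and adjusted p = 0.0439 with an estimated correlation). Apart from CCND1 these were CTNNB1, beta-catenin (-0.97 ± 0.14; -0.89 and -0.16 for its 2 other detected probes, adjusted p = 0.000265 and 0.693), and the receptor gene FZD7 (-0.53 ± 0.16), which missed the threshold without miR-142-3p replicates 1 and 2 and miR-142-3p-1 replicates 2 and 3 (adjusted p = 0.124, 0.15, 0.207 and 0.0971) and with the mean of its probes (adjusted p = 0.323).

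Hypoxia and glycolysis genes included 7 lower with miR-142-3p-1 and none higher, and 14 when adjusted over the list alone (camera adjusted p = 3.45e-05, but adjusted p = 0.106 with an estimated correlation). SLC2A3, BNIP3, PFKP and ANKRD37 had -0.93 ± 0.13, -0.89 ± 0.14, -0.74 ± 0.08 and -0.64 ± 0.14. Of the p53 targets 4 were higher and 1 lower, and 5 and 1 when adjusted over the list alone (camera adjusted p = 0.00156, but adjusted p = 0.0615 with an estimated correlation). SPATA18 was higher by 0.94 ± 0.11 and BAX by 0.52 ± 0.10 (0.26 and adjusted p = 0.0686 with the mean of its probes). DDB2 (0.65 ± 0.17) missed the threshold without miR-142-3p replicates 1 and 2 and miR-142-3p-1 replicates 1 and 3 (adjusted p = 0.103, 0.0778, 0.0793 and 0.0559), and ZMAT3 (-0.45 ± 0.10) missed it with median scaling (adjusted p = 0.0628). ZMAT3 is the 1 lower target, but its 2 other detected probes had 0.41 and 0.14 (adjusted p = 0.0378 and 0.429), and the mean of its probes was 0.03. Of 17 cytosolic heat shock genes 1 was lower and none higher, also when adjusted over the list alone (camera adjusted p = 0.03, but adjusted p = 0.0722 with an estimated correlation and 0.222 with median scaling). It was BAG3 (-0.38 ± 0.11), which missed the threshold without miR-142-3p replicates 1 and 3 and miR-142-3p-1 replicate 1 (adjusted p = 0.0907, 0.0976 and 0.129). The list call ended without miR-142-3p replicate 1 and miR-142-3p-1 replicate 1 (adjusted p = 0.0752 and 0.0837). Actin dynamics regulators gave 7 lower and 4 higher, the same numbers as when adjusted over the list alone (camera adjusted p = 0.953).

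Among the lowest genes with miR-142-3p-1 relative to miR-142-3p were the membrane protein gene BASP1 (-1.38 ± 0.12), CCND1, ANXA3 (-1.33 ± 0.23), SNAR-A1 (-1.25 ± 0.31), MTFR1 (-1.20 ± 0.17), the readthrough gene DNAJC25-GNG10 (-1.20 ± 0.18) and CRABP2 (-1.18 ± 0.14). SNAR-A1 missed the threshold without miR-142-3p replicates 1 and 2 and miR-142-3p-1 replicates 2 and 3 (adjusted p = 0.0621, 0.0744, 0.06 and 0.0592). After ACTA2 the highest were MANBAL (1.29 ± 0.09), PPP1R14C (1.09 ± 0.11), SLC49A4 (1.05 ± 0.12), SLC35F5 (0.98 ± 0.13), SCARNA9 (0.95 ± 0.13), TAF5L (0.95 ± 0.14) and CLDN12 (0.95 ± 0.12). The other detected probe of TAF5L had -0.077 (adjusted p = 0.868). TNFRSF12A had -0.94 ± 0.20 (adjusted p = 0.00628), and TGFBR2 differed by 0.01 ± 0.13 (adjusted p = 0.98). PLA2G7 and ERO1B, not detected with miR-142-3p-1, were at least 1.503-fold and 1.42-fold lower. The count of 1126 genes was 691 without miR-142-3p replicate 2, 735 without miR-142-3p-1 replicate 3 and 681 with only the 6 arrays compared. With median scaling 604 were lower and 156 higher (20.5% higher, against 43.7%), and a log2 fold change of at least 0.5 as well left 486.

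The isomiRs of miR-K10a differed in fewer genes, 142 lower and 107 higher with miR-K10a+1 than with miR-K10a. CPS1 (-1.08 ± 0.11, adjusted p = 6.72e-05), SERF1B (-1.02 ± 0.10, adjusted p = 6.72e-05) and YES1 (-0.99 ± 0.14, adjusted p = 0.00159) were lowest with miR-K10a+1. HYCC2 (0.90 ± 0.13, adjusted p = 0.00163) and DDOST, a subunit of the oligosaccharyltransferase (0.84 ± 0.09, adjusted p = 9.47e-05), were highest. The literature targets of miR-K10a had 0.29 ± 0.20 for TNFRSF12A (adjusted p = 0.541) and 0.28 ± 0.13 for TGFBR2 (adjusted p = 0.308).

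Also lower with miR-K10a+1 than with miR-K10a were ERLIN2 (-0.88 ± 0.11), C9orf78 (-0.85 ± 0.08) and PCBD1 (-0.84 ± 0.10). HDLBP (-0.82 ± 0.19) missed the threshold without miR-K10a replicates 1, 2 and 3 and miR-K10a+1 replicates 1, 2 and 3 (adjusted p = 0.118, 0.0834, 0.0732, 0.0567, 0.127 and 0.0885), and with the mean of its probes it had -0.16 (adjusted p = 0.314). PIGV (-0.81 ± 0.16) missed it without miR-K10a+1 replicates 2 and 3 (adjusted p = 0.0551 and 0.0768). Higher were SYT11 (0.79 ± 0.11), G6PC3 (0.77 ± 0.11), NDRG4 (0.74 ± 0.10; 0.20 and adjusted p = 0.208 with the mean of its probes) and ARFGAP3 (0.73 ± 0.09). ZNF264 (0.81 ± 0.17) was higher but missed the threshold without miR-K10a replicates 1 and 2 and miR-K10a+1 replicates 2 and 3 (adjusted p = 0.0893, 0.0958, 0.086 and 0.0649). IGBP1P1 (0.72 ± 0.17) was higher but missed it without miR-K10a replicates 1 and 2 and miR-K10a+1 replicates 1 and 2 (adjusted p = 0.143, 0.119, 0.0964 and 0.144), and with the mean of its probes it had 0.34 (adjusted p = 0.0757). ACADL and PPIL6, not detected with miR-K10a+1, were at least 1.47-fold and 1.44-fold lower. Of the actin dynamics regulators 2 were lower, also when adjusted over the list alone, and none higher (camera adjusted p = 0.678): RDX (-0.62 ± 0.13) and WASL (-0.35 ± 0.09). RDX missed the threshold without miR-K10a replicates 1 and 2 and miR-K10a+1 replicates 1 and 2 (adjusted p = 0.0735, 0.0833, 0.0714 and 0.0736), and WASL without miR-K10a replicates 1, 2 and 3 and miR-K10a+1 replicates 1, 2 and 3 (adjusted p = 0.124, 0.127, 0.119, 0.156, 0.0844 and 0.0986). Of 63 cytosolic ribosomal proteins 3 were lower and none higher, also when adjusted over the list alone (camera adjusted p = 0.0475, but adjusted p = 0.269 with an estimated correlation and 0.0566 with the replicate block). The ribosomal call ended without miR-K10a replicates 2 and 3 and miR-K10a+1 replicate 2 (adjusted p = 0.08, 0.0718 and 0.107). The 3 lower members were RPL34 (-0.40 ± 0.10), RPS21 (-0.38 ± 0.09) and RPS7 (-0.36 ± 0.09). RPL34 missed the threshold without miR-K10a replicates 1, 2 and 3 and miR-K10a+1 replicates 2 and 3 (adjusted p = 0.109, 0.116, 0.154, 0.196 and 0.106), RPS21 without miR-K10a replicates 1, 2 and 3 and miR-K10a+1 replicates 2 and 3 (adjusted p = 0.128, 0.0879, 0.147, 0.153 and 0.169), and RPS7 without miR-K10a replicates 1, 2 and 3 and miR-K10a+1 replicates 1, 2 and 3 (adjusted p = 0.109, 0.146, 0.081, 0.119, 0.147 and 0.0539). With median scaling RDX, WASL, RPL34, RPS21 and RPS7 missed the threshold too (adjusted p = 0.0735, 0.341, 0.213, 0.185 and 0.213).

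The count of 249 genes between the miR-K10a isomiRs fell whichever array was left out, and fewer arrays leave less to call by construction. It was 75, 61 and 101 without miR-K10a replicate 1, 2 and 3, and 144, 74 and 92 without miR-K10a+1 replicate 1, 2 and 3. It was 78 with median scaling (34 lower, 44 higher), 101 with no detection filter, 140 with only the 6 arrays compared, 406 with array weights and 126 with a log2 fold change of at least 0.5 as well.

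The difference between both isomiR contrasts was tested gene by gene, to ask whether the step from one isomiR to the other had the same effect in both families. It differed for 413 genes, 217 with a lower and 196 with a higher value in the miR-142-3p family. SLC49A4 (1.75 ± 0.16, adjusted p = 4.23e-05) and MANBAL (1.53 ± 0.12, adjusted p = 1.1e-05) had the higher values, and ANXA3 (-1.70 ± 0.32, adjusted p = 0.00758) and BASP1 (-1.33 ± 0.17, adjusted p = 0.000647) the lower. The actin regulators WASL (0.99 ± 0.12, adjusted p = 0.000429) and CTTN (0.86 ± 0.16, adjusted p = 0.00722) also differed. The count was 242 without miR-142-3p replicate 2, and 232, 248 and 254 without miR-K10a replicate 1, 2 and 3. With median scaling it was 273 (229 lower, 44 higher) and with no detection filter 251.

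**Figure D4:**
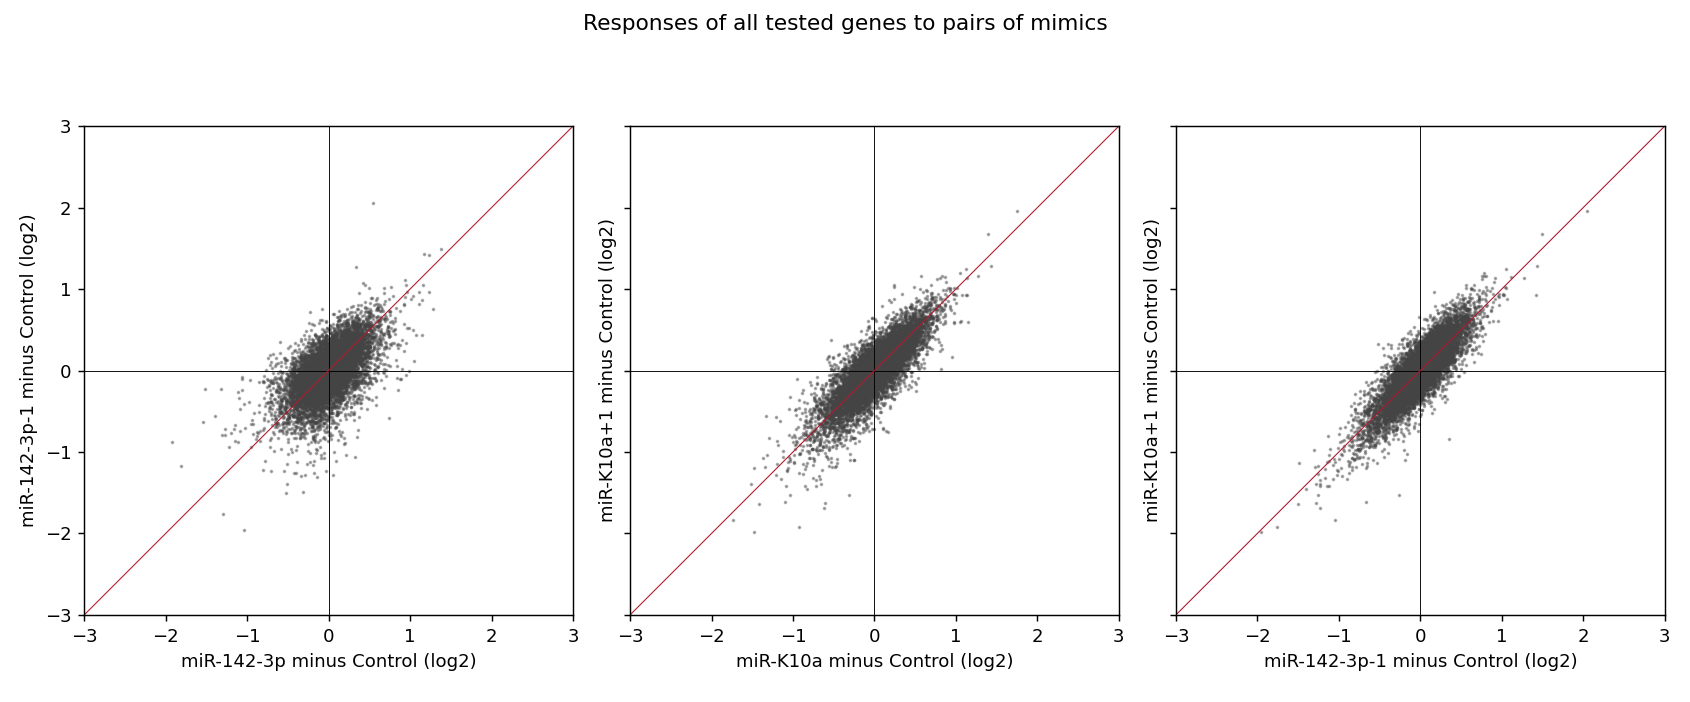
Log2 fold change against the control of 10413 genes (points) for 3 pairs of mimics, one mimic on each axis, with the line of equal response. The Pearson correlations across genes are 0.605 for miR-142-3p and miR-142-3p-1, 0.838 for miR-K10a and miR-K10a+1, and 0.856 for miR-142-3p-1 and miR-K10a+1.

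Across families, miR-142-3p-1 and miR-K10a+1 gave the most alike responses: 843 genes were lower and 827 higher with both, and none changed in opposite directions. Independent calls would give 151 and 165. CCND1, TLCD1, YES1 and RDX fell with both, and ACTA2, PTPMT1 and CDKN1A rose with both. The comparison of these mimics with each other found 3 genes past the threshold in limma, all higher with miR-142-3p-1: C9orf78 (0.91 ± 0.08, adjusted p = 1.96e-05), DHRS7B (0.95 ± 0.12, adjusted p = 0.00198) and TTC8, of the ciliary BBSome complex (0.63 ± 0.10, adjusted p = 0.0273), which missed the threshold without miR-142-3p-1 replicates 1, 2 and 3 and miR-K10a+1 replicates 1, 2 and 3 (adjusted p = 0.181, 0.0546, 0.0602, 0.077, 0.0834 and 0.115). At an unadjusted p below 0.05 there were 1440 genes (13.8%). TNFRSF12A had -0.08 ± 0.20 (adjusted p = 0.896) and TGFBR2 -0.21 ± 0.13 (adjusted p = 0.495), and no list passed camera. The count depended on the setting: 99 with the deposited normalized values, 90 with no background correction, 69 with trend and robust eBayes, 26 with an offset of 50, 12 with every probe on its own, 5 with detection on all 15 arrays, 5 with the replicate block, 5 without miR-142-3p-1 replicate 2 and 6 without miR-K10a+1 replicate 1.

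Between miR-142-3p-1 and miR-K10a, 142 genes were lower and 104 higher with miR-142-3p-1. The metallothionein genes MT1X and MT1F (-0.86 ± 0.14 and -0.83 ± 0.12, adjusted p = 0.00638 and 0.00418) and YES1 (-0.84 ± 0.14, adjusted p = 0.00688) were lowest, and ZNF704 (0.95 ± 0.14, adjusted p = 0.00418), G6PC3 (0.91 ± 0.11, adjusted p = 0.00137) and HYCC2 (0.87 ± 0.13, adjusted p = 0.00418) highest. Interferon-stimulated genes included 2 that were lower and none higher, and 6 lower when adjusted over the list alone (camera adjusted p = 0.034, but adjusted p = 0.23 with an estimated correlation): SP110 (-0.68 ± 0.12), which missed the threshold without miR-K10a replicate 2 (adjusted p = 0.0623) and had -0.34 and -0.69 for its 2 other detected probes (adjusted p = 0.597 and 0.0105), and IRF1 (-0.65 ± 0.11). Canonical histones included 1 that was lower, H2BC11 (-0.74 ± 0.13), and 5 lower when adjusted over the list alone (camera adjusted p = 0.0127, but adjusted p = 0.279 with an estimated correlation). Immediate early genes shifted up as a list (camera adjusted p = 0.0194, but adjusted p = 0.23 with an estimated correlation) although no member passed on its own, and 2 were higher when adjusted over the list alone. The interferon call ended without miR-142-3p-1 replicate 1 and miR-K10a replicate 2 (adjusted p = 0.143 and 0.211), the histone call without miR-142-3p-1 replicate 1 (adjusted p = 0.143) and the immediate early call without miR-142-3p-1 replicate 1 (adjusted p = 0.143). TNFRSF12A had 0.21 ± 0.20 (adjusted p = 0.647) and TGFBR2 0.07 ± 0.13 (adjusted p = 0.825). NEK11, not detected with miR-142-3p-1, was at least 1.44-fold lower, and PCGF5, not detected with miR-K10a, at least 1.38-fold higher. The count of 246 genes was 114, 141 and 156 without miR-142-3p-1 replicate 1, 2 and 3, and 101, 74 and 105 without miR-K10a replicate 1, 2 and 3. It was 100 with median scaling (29 lower, 71 higher), 372 with the deposited normalized values, 397 with no background correction, 380 with trend and robust eBayes, 151 with no detection filter, 88 with only the 6 arrays compared and 129 with a log2 fold change of at least 0.5 as well.

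miR-142-3p stood further from both viral forms, with 886 genes lower and 828 higher than with miR-K10a, and 952 lower and 926 higher than with miR-K10a+1. Relative to miR-K10a, SLC49A4 (-1.45 ± 0.12, adjusted p = 2.65e-06), MANBAL (-1.21 ± 0.09, adjusted p = 2.05e-06) and ACTA2 (-1.20 ± 0.11, adjusted p = 6.16e-06) were lowest. SNAR-A1 (1.95 ± 0.31, adjusted p = 0.00071), ANXA3 (1.47 ± 0.23, adjusted p = 0.000531) and BASP1 (1.35 ± 0.12, adjusted p = 5.96e-06) were highest. Relative to miR-K10a+1, the telomere protein gene TINF2 (-1.41 ± 0.17, adjusted p = 6.53e-05), ACTA2 (-1.41 ± 0.11, adjusted p = 1.2e-06) and BPNT1 (-1.37 ± 0.31, adjusted p = 0.00678) were lowest, and SNAR-A1 (2.05 ± 0.31, adjusted p = 0.000396), DHRS7B (1.497 ± 0.12, adjusted p = 1.16e-06) and CCND1 (1.45 ± 0.10, adjusted p = 6.93e-07) highest.

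Literature targets of miR-142-3p were lower with miR-142-3p than with miR-K10a (8 lower, 1 higher; adjusted over the list alone, 9 and 1; camera adjusted p = 0.000245, and adjusted p = 0.0471 with an estimated correlation). They were also lower than with miR-K10a+1 (6 lower, none higher; adjusted over the list alone, 10 lower; camera adjusted p = 0.00131, and adjusted p = 0.0476 with an estimated correlation). Here too the list may hold genes first reported from these samples. BOD1 had -1.02 ± 0.09 against miR-K10a and -0.62 ± 0.09 against miR-K10a+1, and WASL had -0.95 ± 0.09 and -0.60 ± 0.09. Epithelial markers were higher than with miR-K10a and than with miR-K10a+1, 4 of 5 in each comparison, also when adjusted over the list alone (camera adjusted p = 0.00309 and 0.00392, and adjusted p = 0.0471 and 0.0476 with an estimated correlation). CDH1, detected on 13 of the 15 arrays, had 1.05 ± 0.14 and 0.85 ± 0.14, EPCAM 0.95 ± 0.12 and 0.77 ± 0.12, and KRT8 0.69 ± 0.15 and 0.91 ± 0.15. The 4th, KRT18 (0.46 ± 0.10 and 0.43 ± 0.10), missed the threshold in both with the mean of its probes (adjusted p = 0.0646 and 0.0501), and against miR-K10a+1 without miR-K10a+1 replicate 3 (adjusted p = 0.0559). The other detected probe of KRT18 had 0.17 and 0.24 (adjusted p = 0.476 and 0.305). The Wnt list was higher in both comparisons, with 4 of 12 members past the test in each and 5 each when adjusted over the list alone (camera adjusted p = 0.00978 and 0.00203, but adjusted p = 0.08 with an estimated correlation for miR-K10a, and 0.0476 for miR-K10a+1). CCND1 had 0.71 ± 0.10 against miR-K10a, and CTNNB1 had 0.95 ± 0.14 against miR-K10a+1, where its 2 other detected probes had 0.85 (adjusted p = 0.000222) and -0.064 (adjusted p = 0.869). FZD7 had 0.85 and 0.75, but its other detected probe had -0.15 and -0.23 (adjusted p = 0.595 and 0.404). Against miR-K10a, TCF7L2 and DKK1 missed the threshold in 5 and 4 of 6 fits without 1 array. Against miR-K10a+1, LEF1 missed it in 4 of 6, though its other detected probe passed (0.45, adjusted p = 0.0493).

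Hypoxia and glycolysis genes were higher with miR-142-3p than with miR-K10a (8, none lower, the same number when adjusted over the list alone) and than with miR-K10a+1 (10, none lower, and 11 when adjusted over the list alone). Camera gave adjusted p = 0.0122 and 0.000402, but adjusted p = 0.334 and 0.162 with an estimated correlation. The first call ended without miR-142-3p replicate 2 (adjusted p = 0.103). PFKP had 0.78 ± 0.08 against miR-K10a, and BNIP3 and SLC2A3 had 0.86 ± 0.14 and 0.64 ± 0.13 against miR-K10a+1. Of the p53 targets 3 were lower and 1 higher than with miR-K10a, also when adjusted over the list alone, and 4 lower and 1 higher than with miR-K10a+1, or 7 and 2 when adjusted over the list alone. Camera gave adjusted p = 0.00978 and 0.0427, but adjusted p = 0.13 and 0.196 with an estimated correlation. The second call ended without miR-142-3p replicates 2 and 3 and miR-K10a+1 replicate 3 (adjusted p = 0.0622, 0.0577 and 0.146). The 1 higher was ZMAT3 in both comparisons (0.60 ± 0.10 and 0.57 ± 0.10). Another detected probe of ZMAT3 was past the threshold the other way (-0.50 and -0.52, adjusted p = 0.00966 and 0.00712), and the mean of its probes was -0.033 and -0.028. SPATA18 had -0.80 ± 0.11 in both comparisons and BAX -0.57 ± 0.10 against miR-K10a. Against miR-K10a, 3 immediate early genes were higher, also when adjusted over the list alone, among them ATF3 (0.60 ± 0.13) and JUN (0.45 ± 0.08; camera adjusted p = 0.0335, but adjusted p = 0.13 with an estimated correlation). This call ended without miR-142-3p replicates 2 and 3 (adjusted p = 0.0853 and 0.053). ATF3 had 0.18 (adjusted p = 0.122) with the mean of its probes. In the same comparison 3 canonical histones were lower, also when adjusted over the list alone, among them H2BC11 (-0.89 ± 0.13; camera adjusted p = 0.0335, but adjusted p = 0.334 with an estimated correlation). The histone call ended without miR-142-3p replicates 1 and 2 and miR-K10a replicate 2 (adjusted p = 0.0535, 0.0609 and 0.0913). Against miR-K10a+1, 4 heat shock genes were higher and 5 when adjusted over the list alone, among them HSP90AB1 (0.38 ± 0.09; camera adjusted p = 0.0297, but adjusted p = 0.0874 with an estimated correlation and 0.104 with median scaling). The heat shock call ended without miR-142-3p replicate 1 and miR-K10a+1 replicate 1 (adjusted p = 0.0686 and 0.0698).

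TNFRSF12A was higher with miR-142-3p than with miR-K10a (1.15 ± 0.20, adjusted p = 0.00128) and than with miR-K10a+1 (0.86 ± 0.20, adjusted p = 0.00758), and TGFBR2 had 0.07 ± 0.13 and -0.22 ± 0.13 (adjusted p = 0.769 and 0.259). NTS, which encodes neurotensin and was not detected with either viral form, was at least 1.68-fold and 1.74-fold higher with miR-142-3p. GNG12, not detected with miR-K10a+1, was at least 1.64-fold higher than there. The count of 1714 genes against miR-K10a was 1141 and 1041 without miR-142-3p replicate 1 and 2 and 1077 without miR-K10a replicate 2. That of 1878 against miR-K10a+1 was 1149 without miR-142-3p replicate 2 and 1160 without miR-K10a+1 replicate 2. Median scaling gave 228 lower and 1158 higher against miR-K10a, where it moved the median of all genes to 0.11, and 297 lower and 932 higher against miR-K10a+1. A log2 fold change of at least 0.5 as well left 650 and 699.

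Genes changed in the same direction were shared by every pair of mimics beyond the number that independent calls would give. WASL, TLCD1 and YES1 fell and CDKN1A, PTPMT1 and ANXA1 rose with all 4 mimics; these 6 were picked after their values were seen. miR-142-3p shared 312 lower and 427 higher genes with miR-142-3p-1 (72.0 and 81.3 if independent), 326 and 495 with miR-K10a (89.3 and 120), and 391 and 526 with miR-K10a+1 (107 and 134). miR-142-3p-1 shared 666 and 734 with miR-K10a (126 and 149), and miR-K10a shared 897 and 1125 with miR-K10a+1 (187 and 245). The Pearson correlations of log2 fold changes across genes, which are not independent replicates, were 0.605, 0.576 and 0.599 for miR-142-3p with miR-142-3p-1, miR-K10a and miR-K10a+1. They were 0.797, 0.856 and 0.838 for the other pairs in the order miR-142-3p-1 with miR-K10a, miR-142-3p-1 with miR-K10a+1, and miR-K10a with miR-K10a+1.

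The 3 control arrays that all 4 responses share can give a correlation by themselves. In 100 simulated sets of unchanged groups against shared controls the mean correlation was 0.48, from -0.076 to 0.814. A correlation does not weigh the size of the changes, so the covariance was compared as well, after the result was seen. It averaged 0.0086 in these sets (highest 0.0194). The observed pairs ran from 0.0461 (miR-142-3p with miR-142-3p-1) to 0.088 (miR-K10a with miR-K10a+1). These sets hold no deviation common to all control arrays. The same sets shared 0 called genes, but unchanged groups have hardly any calls to share. Part of the genes shared beyond independent calls may therefore come from these controls. Pairs of contrasts with no array in common had correlations of 0.354 (miR-142-3p-1 minus miR-142-3p with miR-K10a+1 minus the control), 0.31 (the same with miR-K10a minus the control), 0.197, 0.125 and 0.0655. Without Control replicate 1 the genes shared by miR-142-3p were 196 lower and 268 higher with miR-142-3p-1, 208 and 308 with miR-K10a, and 252 and 331 with miR-K10a+1. In the same fit miR-142-3p-1 shared 423 and 453 with miR-K10a and 536 higher with miR-K10a+1, and the miR-K10a forms shared 714 higher. Without Control replicate 3, miR-142-3p and miR-K10a shared 207 lower genes.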

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

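Tests chosen only after the result was seen are the share of genes at an unadjusted p, the covariance of responses, the p53 list between the miR-142-3p isomiRs, and the number of p53 targets higher with all 4 mimics. The change from one isomiR to the other differed between the miR-142-3p and miR-K10a families for 413 genes, by a test of the difference itself. With 100 groupings of the 12 mimic arrays, 1 (the real one) gave as many and the highest other gave 79. A chance sorting of single arrays into groups is thus argued against. A difference between shared cultures is not, since the labels do not say that replicates were separate cultures. Among genes named in either isomiR comparison the difference was negative for ANXA3 (-1.70), BASP1 (-1.33), TNFRSF12A (-1.23), CDH1 (-1.22), EPCAM (-1.18), PFKP (-1.07), CRABP2 (-1.04), G6PC3 (-1.004), DNAJC25-GNG10 (-0.997), IGBP1P1 (-0.99), DDOST (-0.98), SYT11 (-0.92), NDRG4 (-0.87), PKN2 (-0.85), HYCC2 (-0.74), ARFGAP3 (-0.72), SLC2A3 (-0.68) and CCND1 (-0.59). It was positive for RAC1 (0.60), CLIC4 (0.64), BAX (0.66), C9orf78 (0.69), RPL34 (0.83), CTTN (0.86), SCARNA9 (0.90), SPATA18 (0.94), WASL (0.99), BOD1 (1.05), PPP1R14C (1.06), SLC35F5 (1.19), ACTA2 (1.30), MANBAL (1.53) and SLC49A4 (1.75).

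Probes without a gene symbol, which no comparison uses, also responded. Of 3406 such probes tested, 161, 209, 317 and 396 were higher and 124, 163, 292 and 328 lower than in the control with miR-142-3p, miR-142-3p-1, miR-K10a and miR-K10a+1.

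Few genes differed between miR-142-3p-1 and miR-K10a+1, mimics of different families. In the real split 13.8% of genes had an unadjusted p below 0.05, against 7.23% at most in the other 9 splits of the 6 arrays. The real split was thus the highest, but 10 splits are too few for a share under 0.05. Whether the 6 arrays are interchangeable therefore stays open. One mimic under both names cannot be decided this way. Separate cultures or slides could also set the groups apart, and the labels give neither. The covariance of both responses (0.0831) exceeded the highest of 100 simulated sets (0.0194), but these sets hold no deviation common to all control arrays. A common deviation thus stays open. The values argue only against the spread of single control arrays as the whole reason for the likeness. As a part of it the shared controls stay open. The correlation of contrasts with no array in common (0.354) lay below the highest simulated one (0.784), although their covariance (0.0295) exceeded the highest simulated without a shared array (0.0107). No array enters both contrasts, so shared controls cannot give this correlation. The simulated sets were drawn from deviations from group means, which are tied to each other within a group. Their contrasts were therefore not independent, and their range cannot settle what the shared controls add. An effect of related mimic sequences may add to the likeness, and it was not tested. The labels do not give the isomiR sequences, and seed sites could not be searched without transcript sequences.

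The p53 target genes CDKN1A, BAX, TP53I3, SPATA18 and SESN1 were higher with all 4 mimics, although with miR-142-3p BAX had 0.22 (adjusted p = 0.111) with the mean of its probes. A single deviating control array is argued against: over 12 fits without 1 control array the highest camera adjusted p of the list was 0.0367. With an estimated correlation, however, the call ended for miR-142-3p, miR-K10a and miR-K10a+1 (adjusted p = 0.179, 0.079 and 0.0515), and for miR-142-3p it also ended without miR-142-3p replicate 1 (adjusted p = 0.0567). A deviation common to the 3 control arrays cannot be told apart from a response to all 4 mimics, since the rise of these 5 genes rests on the same 3 controls. The list differed between the miR-142-3p isomiRs without use of a control (camera adjusted p = 0.00156), but that call ended with an estimated correlation (adjusted p = 0.0615), so it leaves the question open too, as does an untested stress response to transfected RNA.

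The epithelial markers EPCAM, KRT8, KRT18 and MUC1 were higher with miR-142-3p than with the control, but the other detected probe of KRT18 had 0.021 (adjusted p = 0.946). MUC1 had 0.10 (adjusted p = 0.498) with the mean of its probes, which takes in detected and undetected probes alike. A single deviating array is argued against, as the highest camera adjusted p over the 3 fits without 1 miR-142-3p array was 0.000358. Cells of another type in these wells stay open: 0 of the 11 list members that did not pass the detection filter rose, but most of them were detected on no array, so a small share of other cells need not show. CDH1, detected on 13 of the 15 arrays, had 0.19 ± 0.14 (adjusted p = 0.402). A direct or indirect effect of the mimic on these genes also stays open, as untested.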

How the results depend on the processing

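Alternatives chosen only after the data were examined are the leave-one-out counts of shared genes and the gene lists with median scaling (30 calls), with cyclic loess (24) and without each array (22 to 27); all others were planned. Each comparison's count was recomputed under up to 14 settings besides leaving out arrays, and settings not named here left it within 1.5 times its value. The causes were not tested, except that fewer arrays or a further condition on the fold leave less to call by construction.

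A log2 fold change of at least 0.5 as well gave 584, 830, 1045 and 1287 genes for miR-142-3p, miR-142-3p-1, miR-K10a and miR-K10a+1 against the control, 486 and 126 for the isomiR pairs, 650 and 699 for miR-142-3p against miR-K10a and miR-K10a+1, 129 for miR-142-3p-1 against miR-K10a, and 1920 among the 5 groups. Median scaling gave 859 and 1341 for miR-142-3p and miR-142-3p-1, 78 for the miR-K10a isomiRs, 1229 for miR-142-3p against miR-K10a+1, 100 for miR-142-3p-1 against miR-K10a and 273 for the isomiR difference. Only the 6 arrays compared gave 1028 for miR-142-3p, 681 and 140 for the isomiR pairs and 88 for miR-142-3p-1 against miR-K10a. No detection filter gave 101 for the miR-K10a isomiRs, 151 for miR-142-3p-1 against miR-K10a and 251 for the isomiR difference, and array weights gave 406 for the miR-K10a isomiRs. For miR-142-3p-1 against miR-K10a and miR-K10a+1, the deposited normalized values gave 372 and 99, no background correction 397 and 90, and trend and robust eBayes 380 and 69. The last of these comparisons had 26 with an offset of 50, 12 with every probe on its own, 5 with detection on all 15 arrays and 5 with the replicate block. The 25 list calls became 10 with an estimated correlation, 76 with directional fry and 127 with mixed fry, which do not compare a list with other genes.

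Without 1 array, the counts ranged from 987 to 1356, 1384 to 1886, 1925 to 2681 and 2334 to 3112 for the 4 mimics against the control, 691 to 943 and 61 to 144 for the isomiR pairs, 1041 to 1600, 1149 to 1764, 74 to 156 and 2 to 6 across families, 232 to 372 for the isomiR difference and 3347 to 3996 among the 5 groups. Genes shared lower and higher ranged from 196 to 309 and 268 to 414 (miR-142-3p with miR-142-3p-1), 207 to 350 and 308 to 516 (with miR-K10a), 252 to 418 and 331 to 544 (with miR-K10a+1), 423 to 674 and 453 to 745 (miR-142-3p-1 with miR-K10a), 571 to 841 and 536 to 838 (with miR-K10a+1), and 616 to 926 and 714 to 1172 (miR-K10a with miR-K10a+1). With the deposited normalized values the counts of shared genes stayed within 1.5 times their value. The correlation of responses moved by more than its spread over the fits without 1 array for 4 of the 6 pairs: to 0.633 for miR-142-3p with miR-142-3p-1, 0.82 and 0.881 for miR-142-3p-1 with miR-K10a and miR-K10a+1, and 0.861 for miR-K10a with miR-K10a+1. In the fits without 1 array a group of 2 arrays is assumed to vary like the others. Of 273 comparisons of named genes past the threshold, 235 kept their call in every such fit and 38 lost it in at least 1. Of 41 list calls over 10 comparisons, 27 were kept without each array in turn and 14 were lost without at least 1.

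Reversed values were those of ZMAT3 with the mean of its probes (0.029 between the miR-142-3p isomiRs, -0.033 and -0.028 for miR-142-3p against miR-K10a and miR-K10a+1) and, among values that never passed, TGFBR2 and TNFRSF12A. TGFBR2 between the miR-142-3p isomiRs had -0.092 with median scaling and -0.018 with array weights. It had -0.048 and -0.03 without miR-142-3p replicate 1 and miR-142-3p-1 replicate 1, but kept its sign (0.054) without miR-142-3p replicate 2. Against miR-K10a it had -0.12 for miR-142-3p and -0.11 for miR-142-3p-1 without miR-K10a replicate 3. It kept its sign there (0.177 and 0.185) without miR-K10a replicate 2. TNFRSF12A had -0.030 for miR-142-3p-1 against miR-K10a without miR-142-3p-1 replicate 3, but kept its sign (0.40) without miR-K10a replicate 1. Against miR-K10a+1 it had 0.10 without miR-142-3p-1 replicate 2 and 0.03 without miR-K10a+1 replicate 1. It kept its sign (-0.32) without miR-142-3p-1 replicate 3. No list past camera changed direction with median scaling or cyclic loess. Another detected probe of a named gene had the same sign and passed in 49 of 100 comparisons, had the same sign without passing in 33 and the opposite sign in 18.

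Arrays with the same replicate number did not pair: residuals of same-numbered arrays correlated from -0.0841 to 0.161 (mean 0.0176, against -0.00883 for different numbers). Genes near the detection limit set a floor on how low a fold change can be measured. The planned slide block and the 3 prime UTR seed sites were not run, since the files name no slide and no transcript sequences were available.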

Other observations

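The groups of genes in this part were defined after the data were examined. Genes were grouped by whether they changed with all 4 mimics and by direct tests of miR-142-3p against each of the other 3. The groups overlap: IDH1, for example, was lower with all 4 mimics and also past the test against miR-142-3p for each of the others. Lower with all 4 mimics were 226 genes, among them IDH1, an enzyme of isocitrate metabolism (-0.42 ± 0.10 with miR-142-3p to -1.52 ± 0.10 with miR-K10a+1), the iron transporter gene SLC11A2 (-0.78 ± 0.09 to -1.12 ± 0.09), SHISA2 and EGFR. Higher with all 4 were 336 genes, among them E2F2 (0.95 ± 0.10 to 1.24 ± 0.10) and GSTO2 (0.81 ± 0.12 to 1.27 ± 0.12).

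Lower with the 3 other mimics, and past the test against miR-142-3p for each, were 152 genes. They include the small noncoding RNA BCYRN1, at -0.39 ± 0.13 with miR-142-3p and -1.13 ± 0.13, -1.09 ± 0.13 and -1.42 ± 0.13 with miR-142-3p-1, miR-K10a and miR-K10a+1, and MTFR1, at -0.03 ± 0.17 and -1.23 ± 0.17, -0.85 ± 0.17 and -1.42 ± 0.17. Higher with the 3 others by the same tests were 72 genes, among them TGS1, which modifies RNA caps, and INF2, an actin-nucleating formin (-0.24 ± 0.12 with miR-142-3p against 0.58 ± 0.12, 0.73 ± 0.12 and 0.84 ± 0.12). Lower with miR-142-3p, and past the test against each of the 3 others, were 120 genes, such as RTL8A (-1.28 ± 0.11). Higher by the same tests were 81, such as CALCB, a calcitonin gene-related peptide (1.14 ± 0.13), the receptor ERBB3 (0.98 ± 0.17), APOE, a lipid carrier (0.93 ± 0.13), and PLAT, tissue plasminogen activator (0.90 ± 0.10). A scan of 111 families of genes with a common symbol stem over 6 comparisons (666 tests) found 0 past camera (lowest adjusted p 0.103).

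For each comparison of 3 arrays with 3, the 10 splits of the 6 arrays are too few for a share under 0.05; the real split was the 1 with the highest count each time. The real counts and the highest other were 1557 and 0 for miR-142-3p, 2052 and 1 for miR-142-3p-1, 2791 and 0 for miR-K10a, and 3205 and 0 for miR-K10a+1 against the control. They were 1126 and 0 for the miR-142-3p isomiRs, 249 and 0 for the miR-K10a isomiRs, and 1714 and 0, 1878 and 0, 246 and 1, and 3 and 1 for miR-142-3p against miR-K10a and miR-K10a+1 and for miR-142-3p-1 against the same mimics. Among 100 groupings of the 15 arrays the real one was highest for the 4019 genes that differed among groups (highest other 543). The same held for the 25 list calls over 6 comparisons (highest other 19) and for the 7569 calls shared between mimics, summed over 6 pairs (highest other 3068). Camera with the preset correlation can thus give many list calls under another grouping too. A chance sorting of single arrays is argued against, but not a difference between cultures that a group's arrays may have shared. For the shared calls, the real grouping also had more calls to share.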
